A study of Mus musculus with 24 samples.

How the data were processed

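Gene expression was measured on arrays in 24 mouse samples, 8 of a cell line and 16 of primary leukaemias. BKO408 is a precursor B-cell acute lymphoblastic leukaemia (preB-ALL) line from a Blnk knockout mouse, grown with IL-7. BKO408 cells were measured on 4 arrays and BKO408 cells transduced with a retrovirus for LAP, the activating form of the transcription factor C/EBPβ encoded by Cebpb, on 4 arrays. The tumours were 5 preB-ALL of Blnk knockout mice (Blnk tumours), 3 preB-ALL of Blnk knockout mice carrying a LAP transgene (LAP/Blnk tumours), 4 preB-ALL of LAP transgenic mice (LAP preB-ALL) and 4 B-ALL of LAP transgenic mice (LAP B-ALL). The tissue the tumours were taken from, the share of tumour cells in it, the mouse strain, the sex of the animals, the control treatment of the BKO408 cells and the dates of hybridisation are not given in the sources used here. The labels do not say whether replicates of the cell line were separate cultures or whether each tumour came from another animal, so p-values measure the spread between these samples.

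Per the labels, total RNA was made into biotin-labelled cRNA for an Affymetrix array. MAS5 is the only tool in the submitters' processing notes, and its version is not given in the sources used here. The deposited values are log ratios and were taken as log2. The base of the logarithm is not given in the sources used here. The widest range of a probe set over the tumours was 10.9 log units, which is a ratio of 1884 in base 2 and of 53063 in natural logarithms. The median of each of the 45141 probe sets was 0 over the 8 cell-line arrays and, separately, 0 over the 16 tumours. Each deposited log2 ratio is therefore relative to the median of its own set of arrays, and no level of expression, intensity or detection call was kept. How the arrays were scaled before this centring is not given in the sources used here. For the same reason the planned comparison of Blnk tumours with BKO408 cells was left out, as were the planned pseudocounts and filters on low values. The number of arrays limits the precision.

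Probe sets were named from an annotation table of 2016. A single gene symbol was held by 28898 probe sets, several by 551, and none by 15692, of which 104 were controls. Of the probe sets with a single symbol, 28689 matched a gene of the assembly GRCm38.p6, which was used for names, chromosomes and the order of neighbouring genes only, and 0 symbols had to be updated. Each of 17097 genes was tested with its probe set of the largest spread around the means of the cell-line and of the tumour arrays, with groups ignored, and 7180 genes had more than 1 probe set. The plan had named the probe set with the highest mean level, which centred values do not have.

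Groups were compared with limma 3.58.1 in R 4.3.3, with linear models and moderated tests, two-sided, and Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. The cell-line arrays were fitted together, as were all 16 tumours, and LAP and control cells, LAP/Blnk and Blnk tumours were fitted together for the difference of both LAP effects. The plan had a variance that follows the mean. The mean of centred values is not a level, and such a trend gave prior variances of up to 62427000 in the tumour fit against 0.037 without it, so the fit without a trend, foreseen in the plan, was used and the trend became an alternative. Standard errors (SE) are those of the moderated test. Single probe sets of Cebpb and Blnk were compared with exact permutation tests, two-sided, adjusted over 20 tests.

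Before the data were examined, 24 lists with 485 genes were fixed, of which 431 genes were measured. The genes without a value included Igll1, Il7r and Cebpe. The process lists were pre-B-cell receptor (pre-BCR) components and signalling, V(D)J recombination and early pro-B genes, B-lineage transcription factors, immature and mature B-cell genes, inflammatory genes with C/EBP sites, IL-7 receptor and STAT5 response, Myc and ribosome biogenesis, cell cycle, p53 response, unfolded protein and amino-acid stress, interferon response, immediate early and dissociation stress genes (immediate early genes below), stem and progenitor genes, cholesterol biosynthesis, and glycolysis and hypoxia. The lists of other cells were plasma cells, granulocytes, monocytes and macrophages, T cells, NK cells, erythroid cells and platelets, stroma and endothelium, and dendritic cells. The last list held sex-linked genes. Of these, 23 were tested with limma's camera, with a preset correlation between genes of 0.01 and, as an alternative, an estimated one, adjusted over the lists of a comparison. Members that changed were counted over all genes and adjusted over the list alone.

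The genes named in the text follow a rule also fixed before the data were examined. It took every probe set of Cebpb and Blnk, and the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap. Rearranged immunoglobulin and T-cell receptor segments, sex-linked genes and unnamed transcripts were counted and not named. Where no gene passed, the 5 with the smallest p were taken. It also took up to 4 members of each list by smallest p and a fixed panel of 20 genes of B-cell stages, myeloid cells and their regulators, some of which had no value. For the difference of both LAP effects it took the 5 highest and 5 lowest.

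The genes changed at least 2-fold in the cell line were tested as sets in LAP/Blnk against Blnk tumours. Other splits of the same samples were tested, at most 100 for each comparison. Alternatives were quantile normalisation, the mean of all probe sets of a gene, array weights, a 2-fold threshold, other sets of arrays in the fit, a block for the replicate number, leaving out each replicate, and, chosen after seeing the data, array medians set to 0, a probe set chosen by its name, the more variable genes, a trend of the variance, Xist as a covariate, tumours without replicate 4 of LAP B-ALL, and separate variances for tumours and cells. The block was fitted to the groups compared alone, and only to samples whose replicate number both groups held. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

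The procedure was tested on simulated data with the within-group spread of the 17097 genes, in which 50 genes were changed by each of 0.5, 1, 2 and 4 on the log2 scale. In the cell-line comparison 46 of 50 genes changed by 0.5 were recovered and 50 of 50 at each larger change, with 13 false calls. For LAP/Blnk against Blnk tumours 16, 34, 45 and 48 were recovered in order of size, with 8 false calls. For LAP/Blnk tumours against LAP preB-ALL these were 14, 29, 46 and 50, with 9 false calls. For LAP preB-ALL against Blnk tumours they were 20, 29, 39 and 50, with 8 false calls. For LAP B-ALL against LAP preB-ALL they were 15, 26, 44 and 48, with 3 false calls.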

Results

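Expression ratios of 17097 genes were compared in 6 groups of mouse samples: BKO408 cells (n = 4), BKO408 cells with LAP (n = 4), Blnk tumours (n = 5), LAP/Blnk tumours (n = 3), LAP preB-ALL (n = 4) and LAP B-ALL (n = 4). All values are log2 ratios to the median of the 8 cell-line arrays or of the 16 tumours, so cells and tumours have separate baselines. The median SD of a gene within a group was 0.0602 in BKO408 cells, 0.0502 with LAP, 0.207 in Blnk tumours, 0.157 in LAP/Blnk tumours, 0.236 in LAP preB-ALL and 0.188 in LAP B-ALL.

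Cebpb and Blnk were read in every sample as a check of the labels. Of 3 Cebpb probe sets, the one with the largest spread was at -3.99, -3.33, -3.19, -4.50 and -1.94 in Blnk tumours 1 to 5 and at 0.51, -0.03 and 0.27 in LAP/Blnk tumours 1 to 3. In LAP preB-ALL 1 to 4 it was at 0.03, -1.41, 0.05 and 0.19, and in LAP B-ALL 1 to 4 at 0.29, 0.90, 0.14 and -3.11. The tumour labelled LAP B-ALL 4 therefore lay within the range of tumours without the transgene. LAP/Blnk tumours exceeded Blnk tumours by 3.64 ± 0.78 (SE; exact permutation p = 0.0179, the smallest this design allows; 0.179 adjusted over 20 tests). LAP preB-ALL exceeded Blnk tumours by 3.10 ± 0.71 (exact p = 0.0159, adjusted 0.179). Neither difference passed the test over all genes, with limma adjusted p of 0.189 and 0.107. The other 2 Cebpb probe sets differed between LAP/Blnk and Blnk tumours by -0.42 and 0.38 (exact p = 0.643 and 0.0714). In BKO408 cells with LAP the 3 Cebpb probe sets differed from control by 0.15 ± 0.06 (that of the largest spread, exact p = 0.0571), 0.06 and -0.07, so no probe set showed the transduction by a test. Which part of Cebpb these probe sets cover, and which part the virus carries, is not given in the sources used here, and a probe outside the introduced part checks nothing.

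The single Blnk probe set was at -0.53, -0.68, 0.94, -0.17 and -0.55 in Blnk tumours 1 to 5 and at 0.42, 0.52 and 1.23 in LAP/Blnk tumours. It was at 0.01, 1.45, -0.06 and -0.01 in LAP preB-ALL and at 0.93, -0.32, -0.53 and 0.85 in LAP B-ALL. The means of Blnk tumours and LAP preB-ALL were -0.20 and 0.35, a difference of 0.54 that did not pass (exact p = 0.325), and the groups overlapped through Blnk tumour 3 alone. LAP/Blnk tumours, which are knockouts too, had the highest mean of the tumour groups (0.72), against the direction of the label. Blnk lies on chromosome 19, whose genes lay higher in LAP/Blnk tumours (below). The probe set therefore does not settle the knockout label. The deleted part of Blnk is not given in the sources used here, and a probe outside it checks nothing. In BKO408 cells with LAP Blnk fell by 0.10 on the log2 scale (SE 0.03, limma adjusted p = 0.0201), but the exact test did not pass after adjustment (exact p = 0.0286, the smallest possible; adjusted 0.19).

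The cell-line comparison asked what LAP changes in preB-ALL cells that lack Blnk. Ccl9, a chemokine of myeloid cells, rose by 3.85 ± 0.05 (SE, n = 4 and 4; 14.4-fold). Slpi, a protease inhibitor, rose by 2.54 ± 0.03, Cybb, the phagocyte oxidase subunit, by 2.29 ± 0.05 and Ccr2, a monocyte chemokine receptor, by 2.25 ± 0.18. Fndc3b rose by 2.09, Ctxn3 by 1.68, the immediate early gene Fos by 1.56, the lysozyme gene Lyz2 by 1.53, Csprs by 1.52 and Angptl6 2.84-fold. The potassium channel gene Kcnf1 fell by 2.48 (SE 0.05; 5.57-fold). Dntt, the terminal transferase of early B cells, fell by 1.91 (SE 0.03), the recombinase gene Rag1 by 1.32 and the transcription factor gene Irf4 by 1.41. Kynu fell by 1.65, St3gal6 by 1.56, Gimap4 by 1.38, Colec12 by 1.33, Prodh by 1.30 and Crisp3 by 1.29.

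In total 3820 of 17097 genes passed (22.3%), 1801 higher and 2019 lower with LAP, with a median change of 0.19 in size. With all 24 arrays in the fit, which pools the wider spread of tumours with that of cells, 21 genes passed, and of the cell-line genes named here those were Fndc3b, Angptl6, Kcnf1, Prodh and Ero1a. At least 2-fold changes were seen in 28 higher and 19 lower genes. Groups did not overlap in 4578 genes (26.8%), against 2.86% by chance. The called genes included 191 unnamed transcripts and 5 rearranged segments. Of the panel, Vpreb1 (0.01), Ms4a1 (0.01), Csf3r (0.00), Mpo (-0.07), Csf1r (0.04), Cebpa (-0.01), Cebpd (0.04), Pax5 (-0.12), Spi1 (-0.12), Kit (-0.06) and Il2ra (-0.11) did not pass, while Myc rose by 0.21 and Ebf1 fell by 0.20 (adjusted p = 0.0412).

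**Figure D1:**
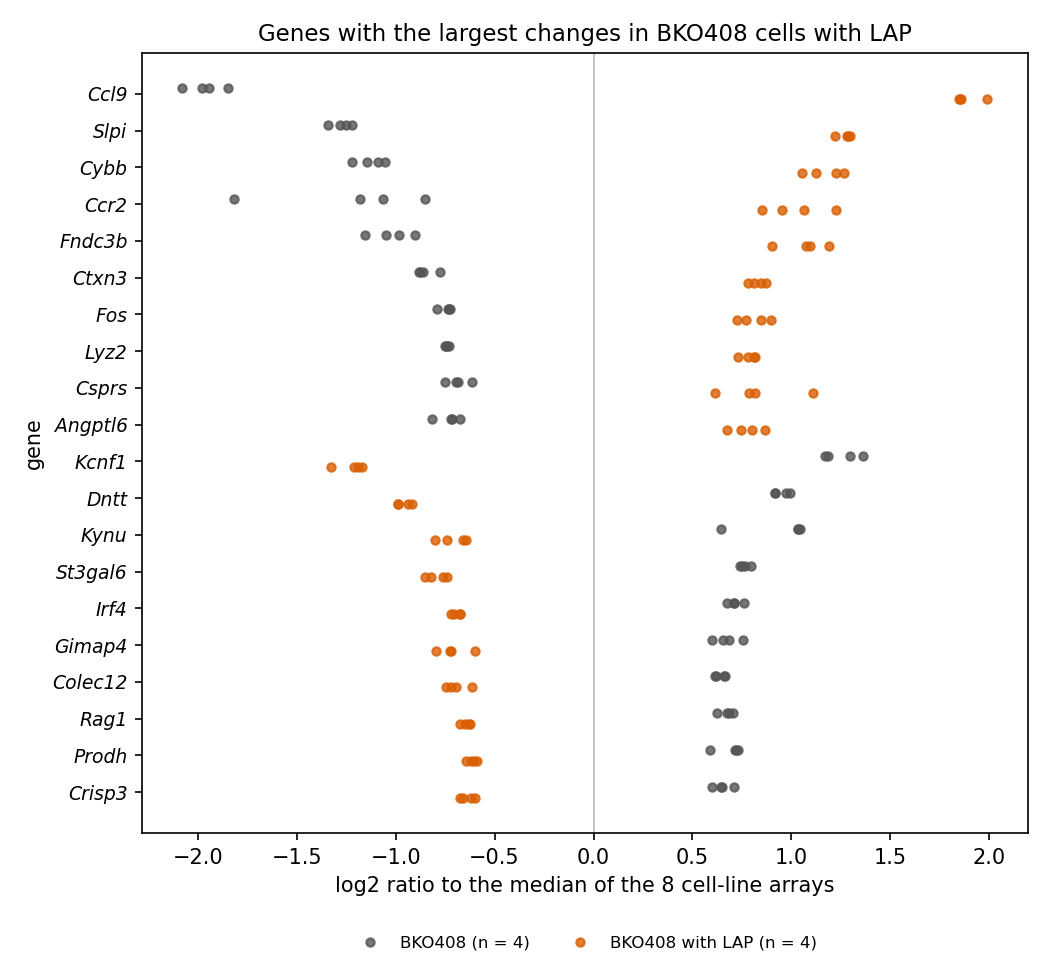
Log2 ratios to the median of the 8 cell-line arrays for the 10 genes with the largest rises and the 10 with the largest falls, each point an array, grey for BKO408 cells (n = 4) and orange for BKO408 cells with LAP (n = 4). The 20 genes were chosen among those past the threshold whose groups did not overlap, and the widest difference was that of Ccl9 (3.85).

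Among B-cell genes in the cell line, V(D)J recombination and early pro-B genes fell, with 7 of 14 members lower and 0 higher (9 lower adjusted over the list alone). Rag2 fell by 1.19 and the cytokine receptor gene Flt3 by 0.71 beside Dntt and Rag1, and the list differed from other genes by camera (adjusted p = 4.15e-07; adjusted p = 0.00916 with an estimated correlation). Of 20 B-lineage transcription factors 11 fell and 1 rose, the same numbers adjusted over the list alone, among them Bach2 (-0.51), Id3 (-0.52) and Ets1 (-0.37) (camera adjusted p = 3.95e-05; adjusted p = 0.0788 with an estimated correlation). Pre-BCR genes moved both ways, with 1 higher and 3 lower of 18 (2 and 3 adjusted over the list alone), Prkcb at -0.46, Dok3 at -0.26, Malt1 at -0.17 and Cd79b at 0.13 (camera adjusted p = 0.429). Immature and mature B-cell genes had 3 higher and 6 lower of 24 (3 and 7 adjusted over the list alone), with Tnfrsf13c at -0.67, Cd22 at -0.59, Cd72 at -0.50 and Cd69 at 0.57 (adjusted p = 0.413). Plasma-cell genes had 3 higher and 1 lower of 9 (4 and 1 adjusted over the list alone), with Creld2 at 0.19 and Irf4 at -1.41 (adjusted p = 0.429).

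In the cell line 19 of 21 Myc and ribosome biogenesis genes rose and 0 fell (20 and 0 adjusted over the list alone), among them Ppan (0.48), Srm (0.46), Mycn (0.39) and Wdr43 (0.31) (camera adjusted p = 2.45e-14; adjusted p = 0.00276 with an estimated correlation). Of 16 cholesterol biosynthesis genes 14 fell and 0 rose, also adjusted over the list alone, among them Insig1 (-0.69), Msmo1 (-0.62), Fdps (-0.58) and Fdft1 (-0.54) (camera adjusted p = 1.72e-13; adjusted p = 0.0089 with an estimated correlation). Immediate early and dissociation stress genes rose, 10 of 18 with 1 lower (11 and 1 adjusted over the list alone), with Klf2 at 1.19 and Egr1 at 0.84 (camera adjusted p = 4.15e-07; adjusted p = 0.0186 with an estimated correlation). Whether the handling of the samples moved this list was not tested. Of 20 interferon response genes 9 fell and 0 rose (10 adjusted over the list alone), with the guanylate-binding protein genes Gbp2 at -1.04 and Gbp3 at -0.75 (camera adjusted p = 2.44e-04; adjusted p = 0.084 with an estimated correlation). Cell-cycle genes had 3 higher and 16 lower of 33 (3 and 17 adjusted over the list alone), with Ccne2 at -0.35 and Aurka at 0.23 (camera adjusted p = 0.00925; adjusted p = 0.469 with an estimated correlation).

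The remaining lists did not pass camera in the cell line, though members changed. Of the p53 response genes 4 rose and 5 fell, also adjusted over the list alone, with the cell-cycle inhibitor gene Cdkn1a at 1.44, Btg2 at -0.69, Trp53inp1 at -0.57 and Cdkn2c at -0.42 (adjusted p = 0.888). Unfolded protein and amino-acid stress genes had 6 higher and 7 lower (6 and 8 adjusted over the list alone), with Trib3 at 0.93, Ddit3 at 0.63 and Chac1 at -0.37 (adjusted p = 0.855). IL-7 receptor and STAT5 response genes had 4 higher and 3 lower (4 and 4 adjusted over the list alone), with Pim1 at 0.50, Cish at 0.38 and Igfbp4 at -0.47 (adjusted p = 0.605). Glycolysis and hypoxia genes had 4 higher and 2 lower (5 and 3), with Ero1a at 0.98 and Vegfa at 0.53 (adjusted p = 0.343), and stem and progenitor genes 1 higher and 3 lower, with Bmi1 at 0.25 (adjusted p = 0.48). Inflammatory genes with C/EBP sites had 3 higher and 0 lower of 22, also adjusted over the list alone, with the chemokine gene Ccl3 at 1.43, Tnf at 0.30 and Socs3 at 0.27 (adjusted p = 0.413). Granulocyte genes had 3 higher and 1 lower of 20 (4 and 1 adjusted over the list alone), with the repressor gene Gfi1 at 1.27, Mmp8 at 0.45, Prtn3 at 0.44 and Elane at -0.12 (adjusted p = 0.343). Monocyte genes had 4 higher and 1 lower of 21 (5 and 2 adjusted over the list alone), with Ccr2 and Lyz2 as above, Fcgr1 at 0.41 and Ctss at -0.20 (adjusted p = 0.413). T-cell markers had 1 higher and 2 lower (Cd28 at 0.73, adjusted p = 0.653), NK-cell markers 0 and 2 (Klrb1c at -0.40, adjusted p = 0.707), and erythroid, stromal and dendritic markers 0 and 1 each (Car2 at -0.23, adjusted p = 0.989; Pecam1 at -0.55, adjusted p = 0.343; Flt3, adjusted p = 0.343). No sex-linked gene passed (Xist at -0.01).

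The comparison of LAP/Blnk with Blnk tumours asked what LAP adds to tumours of Blnk knockout mice. Fgf12, an intracellular fibroblast growth factor homologue, rose by 3.54 ± 0.41 (n = 3 and 5; 11.6-fold; limma adjusted p = 0.0112). B3galt1, a galactosyltransferase gene, rose by 2.22 ± 0.27 (4.65-fold; adjusted p = 0.0112) and Shoc2, a scaffold of Ras signalling, by 0.87 ± 0.12 (1.82-fold; adjusted p = 0.0353). Fgf12 was at 3.16, 3.35 and 3.97 in LAP/Blnk tumours and between -0.17 and 0.05 in Blnk tumours, and at 2.42 in LAP preB-ALL 1. B3galt1 did not pass with the probe set chosen by name or without LAP/Blnk tumour 2 (2.16), and Shoc2 did not pass with the mean of probe sets, with only these groups in the fit, in the more variable genes, with a trend of the variance, without LAP/Blnk tumours 1 (0.84) or 2 (0.83) or without Blnk tumours 1 (0.80), 2 (0.81), 3 (0.89) or 5 (0.87). The count was 8 and 13 without LAP/Blnk tumours 1 and 3, 33 with array weights and 29 with quantile normalisation. These were the 3 genes that passed, all higher, and 989 genes were under an unadjusted p of 0.05, where 855 were expected by chance. Of the 989 genes 492 were higher and 497 lower, and chromosome 19 alone held 190 of the higher ones. The excess over 855 therefore does not show a change across all chromosomes. With a block for the replicate number no gene passed, so Fgf12 and B3galt1 lost their calls as well. That fit held only tumours 1 to 3 of both groups and none of the other groups. The loss therefore cannot be put down to the block rather than to the samples left out. Groups did not overlap in 917 genes (5.36%), against 3.57% by chance. In the panel Vpreb1 (0.30), Rag1 (0.40), Dntt (0.13), Ms4a1 (-3.30, SE 1.80), Myc (0.15), Mpo (-0.62) and Lyz2 (-0.34) did not pass. The spread within all tumour groups entered these tests. For Vpreb1 the SE was 2.30, against SDs of 0.06 in LAP/Blnk and 0.26 in Blnk tumours. Its test was therefore limited by the spread within the LAP preB-ALL and LAP B-ALL groups.

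Among lists in that comparison, interferon response genes lay lower, with 19 of 20 members negative and a median of -0.98 (camera adjusted p = 2.5e-08; adjusted p = 0.924 with an estimated correlation). No member passed over all genes (3 fell adjusted over the list alone), with Usp18 at -2.23, Rtp4 at -1.67 and Ifit3 at -1.58. The list median was -0.93, -0.91 and -0.79 in LAP/Blnk tumours and -1.11, 0.13, 0.72, -0.13 and 0.68 in Blnk tumours 1 to 5. Monocyte genes (adjusted p = 0.00503) and Myc and ribosome genes (adjusted p = 0.00606) lay lower and cell-cycle genes higher (adjusted p = 0.00606), each with adjusted p = 0.924 with an estimated correlation. The other lists did not pass, the nearest being granulocyte genes (adjusted p = 0.0545), with Gfi1 at -1.25. Their list median was 2.73 in Blnk tumour 5, between -0.67 and 0.05 in the other Blnk tumours and 0.36, -0.35 and -0.74 in LAP/Blnk tumours, so the lower mean with LAP rests on 1 Blnk tumour.

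Genes of chromosome 19 lay higher in LAP/Blnk tumours than in Blnk tumours. The median difference over its 568 genes was 0.24, with 72.5% positive, and it was -0.03 over genes of the other autosomes. The chromosome's median, set against the other autosomes of the same array, was 0.22 to 0.38 in the 3 LAP/Blnk tumours and -0.12 to 0.06 in the other 13 tumours. The exact p against Blnk tumours was 0.0179, the smallest possible, and 0.357 adjusted over 20 chromosomes, while camera gave an adjusted p of 3.73e-29 (adjusted p = 0.0105 with an estimated correlation). Shoc2 and Ms4a1 lie on this chromosome.

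The comparison of LAP/Blnk tumours with LAP preB-ALL asked what the loss of Blnk adds to LAP. Gfra1, the receptor of glial cell-derived neurotrophic factor, rose by 4.80 ± 0.79 (n = 3 and 4; 27.9-fold). Spsb4 rose by 4.24 ± 0.41, Pcp4l1 by 4.04, Stambpl1 by 3.84, Ankrd6 by 3.80, Smtnl2 by 3.67, the clock gene Arntl by 3.31, Klrb1c by 3.20, Robo3 by 3.18 and Tifa by 3.07. Csprs fell by 4.21 (SE 0.95; 18.5-fold), the cyclin gene Ccnd2 by 3.99 (adjusted p = 0.0496) and Bcl3 by 2.79, with the cohesin release gene Wapl at -3.21. Ifi47 fell by 2.22, Ly86 by 1.92, the DNA sensor gene Cgas by 1.87, Eef1akmt1 and Bmp2k by 1.82 each and Dhx58 by 1.81. In total 406 genes passed, 272 higher and 134 lower, and 3082 were under an unadjusted p of 0.05. Chromosome 19 held 119 of the 272 higher genes and 1 of the lower, among them Gfra1 and Stambpl1, and its median difference was 0.32. The count was 132, 134 and 85 without LAP/Blnk tumours 1, 2 and 3, 237, 215 and 230 without LAP preB-ALL 1, 3 and 4, and 50 with only these groups in the fit. With a block for the replicate number, in a fit without LAP preB-ALL 4 and without the other groups, no gene passed.

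Id3, an inhibitor of E proteins, rose in that comparison by 2.45 ± 0.46 (adjusted p = 0.0196), Cdkn2c by 1.39, the kinesin gene Kif11 (chromosome 19) by 1.57, Stard4 by 0.79 and Col1a2 by 0.33, and Pfkl fell by 1.08. Rag1 (5.15, adjusted p = 0.157), Rag2 (4.09), Erg (3.67), Vpreb1 (4.66), H2-DMb2 (-3.81) and Usp18 (-2.57) did not pass. None of the 10 lists that passed camera with the preset correlation passed with an estimated one (adjusted p = 0.546 each). Interferon response genes lay lower with the preset one (adjusted p = 1.34e-05; 3 adjusted over the list alone), as did glycolysis (adjusted p = 0.00718; 1 lower, 5 adjusted over the list alone), Myc and ribosome (adjusted p = 0.011; 5 adjusted over the list alone), immature and mature B-cell (adjusted p = 0.0169; 2 adjusted over the list alone), T-cell and dendritic genes (adjusted p = 0.0169 each). V(D)J genes (adjusted p = 0.00966; 4 higher and 1 lower adjusted over the list alone), B-lineage transcription factors (adjusted p = 0.013; 1), stromal markers (adjusted p = 0.00718; 1) and cell-cycle genes (adjusted p = 0.0169; 1) lay higher. The V(D)J median ran from 0.27 to 0.63 in LAP/Blnk tumours and from -2.67 to -0.001 in LAP preB-ALL. Much of that shift rests on LAP preB-ALL 2 and 4, where the median was low.

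The comparison of LAP preB-ALL with Blnk tumours set the 2 single lesions against each other. Spsb4 fell by 2.94 (SE 0.36, n = 4 and 5; 7.68-fold; adjusted p = 0.0186), Id3 by 2.77 (SE 0.41) and Rnf144a by 2.47. Sptbn1 fell by 1.78, Vash2 by 1.53, the ephrin receptor gene Epha2 by 1.39, the Wnt regulator gene Apc by 1.04, the splicing factor gene Srsf3 by 0.83, Papola by 0.82 and Hnrnpr by 0.80. Of 14 genes that passed 13 were lower, the others being Elf2 (-0.64), Osbpl11 (-0.71) and 1 unnamed transcript, and 2255 were under an unadjusted p of 0.05. The single higher gene, AI413582 (1.18), was named after its value was seen. None of the 10 named genes passed with the mean of probe sets, with the probe set chosen by name or without LAP preB-ALL 2. With a block for the replicate number, in a fit without Blnk tumour 5 and without the other groups, none passed either. The count was 4, 0 and 5 without LAP preB-ALL 1, 2 and 3 and 8, 2, 2 and 6 without Blnk tumours 1 to 4, but 24 with array weights and 107 without LAP B-ALL 4. Rag1 (-4.75, adjusted p = 0.233), Rag2 (-3.34), Bach2 (-3.32), Flt3 (3.19), H2-DMa (2.58), Col3a1 (-2.91) and Cdkn2c (-0.98, adjusted p = 0.0735) did not pass. Stromal markers (adjusted p = 0.00324), V(D)J genes and B-lineage transcription factors (adjusted p = 0.00576 each) lay lower by camera, and cholesterol (adjusted p = 0.0111), glycolysis (adjusted p = 0.0138) and dendritic genes (adjusted p = 0.0439) higher, each with adjusted p = 0.793 with an estimated correlation. Adjusted over the list alone, 4 V(D)J genes were lower and 1 higher. The stromal median was 1.52 in Blnk tumour 5 and between -0.09 and 0.08 in the other Blnk tumours, against -0.20, -0.70, 0.43 and -0.34 in LAP preB-ALL 1 to 4. The V(D)J median was -0.14, -2.67, 0.00 and -2.61 in LAP preB-ALL 1 to 4, so much of the stromal shift rests on Blnk tumour 5 and of the V(D)J shift on LAP preB-ALL 2 and 4.

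The comparison of LAP B-ALL with LAP preB-ALL asked how tumours labelled B-ALL differ from those labelled preB-ALL under the same transgene. No gene passed limma's test (smallest adjusted p = 0.125), and 1886 genes were under an unadjusted p of 0.05. The count was 5 without LAP B-ALL 4 and 291 without LAP preB-ALL 4. The genes with the smallest p, which did not pass, were Pml (1.70 ± 0.24), Cdadc1 (1.36), Spty2d1 (0.79), Akna (0.98) and Pgrmc1 (-0.71). Ms4a1, which encodes the B-cell antigen CD20, was at 3.57 ± 1.74, S100a8 at 5.34, Hba-a1 at 4.03, Alas2 at 4.01, Syk at 1.30, Klf2 at 2.25, Id3 at 2.18, Pdk1 at -1.22 and Sqle at -1.41, none passing. Erythroid and platelet markers lay higher, with 17 of 17 positive and a median of 2.57 (camera adjusted p = 1.07e-07; adjusted p = 0.355 with an estimated correlation). Granulocyte genes lay higher (adjusted p = 1.45e-06; adjusted p = 0.406 with an estimated correlation), as did monocyte genes (adjusted p = 1.45e-06; 0.355), immature and mature B-cell genes (adjusted p = 2.29e-04; 0.418), pre-BCR (adjusted p = 0.00644; 2 adjusted over the list alone; 0.355), immediate early (adjusted p = 0.00907; 2; 0.355) and B-lineage factor genes (adjusted p = 0.00937; 1; 0.406). Myc and ribosome genes (adjusted p = 1.45e-06; 0.406), glycolysis (adjusted p = 1.45e-06; 3; 0.355), cholesterol (adjusted p = 2.68e-06; 3; 0.355) and cell-cycle genes (adjusted p = 0.0387; 0.72) lay lower, the last value of each being the adjusted p with an estimated correlation.

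Within groups the tumours were not alike. Vpreb1, a surrogate light chain gene of pre-B cells, was at -0.11, -8.49, 0.01 and -8.89 in LAP preB-ALL 1 to 4 and at -8.84, -8.78, -8.97 and 0.14 in LAP B-ALL 1 to 4. It lay between -0.45 and 0.35 in all Blnk and LAP/Blnk tumours. Rag1 was at -3.71, -6.24, -0.41 and -5.66 in LAP preB-ALL and at -6.13, -6.62, -6.11 and 2.00 in LAP B-ALL. Ms4a1 was at -3.87, 3.87, -4.67 and 1.94 in LAP preB-ALL and at 3.68, 2.96, 3.06 and 1.85 in LAP B-ALL. The erythroid list median was at 4.85, 5.04, 5.79 and 0.26 in LAP B-ALL and at -0.31, -0.09, -0.06 and 5.70 in LAP preB-ALL, which places erythroid transcripts in LAP B-ALL 1, 2 and 3 and in LAP preB-ALL 4. Xist was high in 2 of 5 Blnk tumours, 1 of 3 LAP/Blnk tumours, 2 of 4 LAP preB-ALL and 4 of 4 LAP B-ALL, so the groups differed in their share of tumours with Xist.

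**Figure D2:**
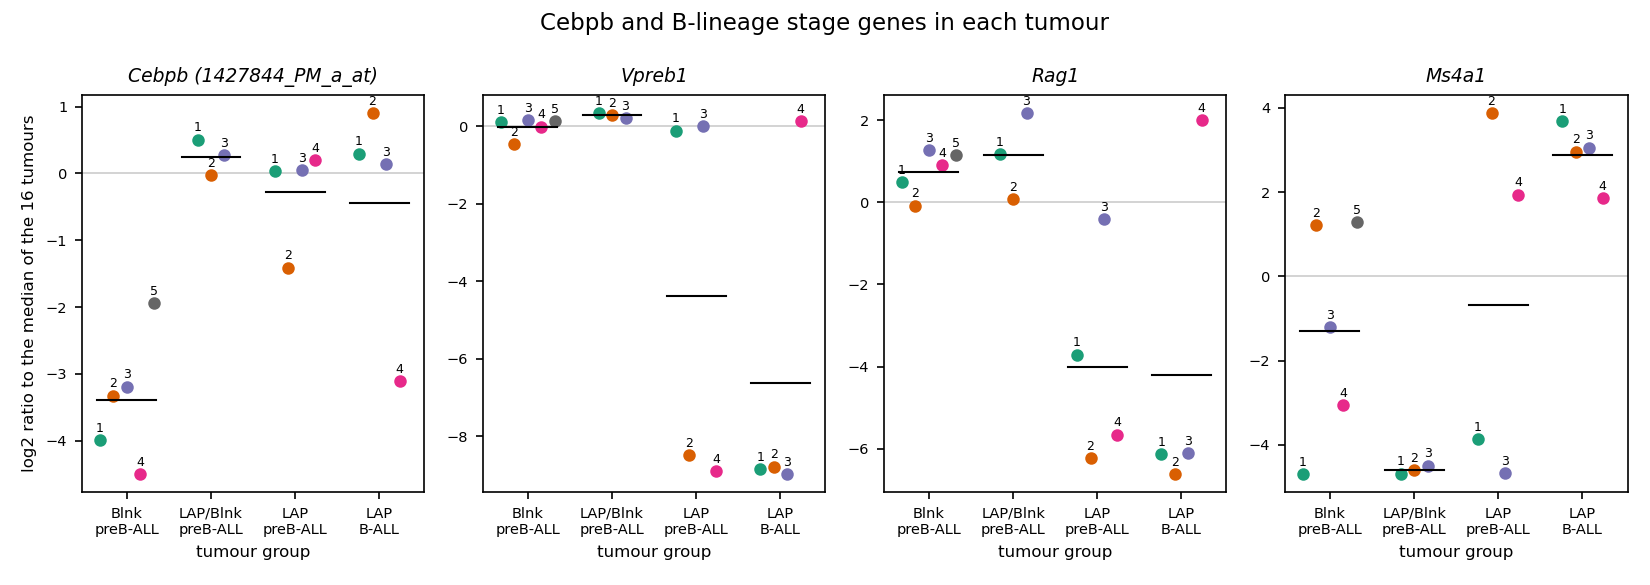
Log2 ratios to the median of the 16 tumours for the Cebpb probe set of the largest spread, Vpreb1, Rag1 and Ms4a1 by tumour group, each point a tumour with its replicate number and each line a group mean (n = 5, 3, 4 and 4). LAP B-ALL 4 lies at -3.11 for Cebpb and at 0.14 for Vpreb1, apart from the other LAP B-ALL tumours.

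**Figure D3:**
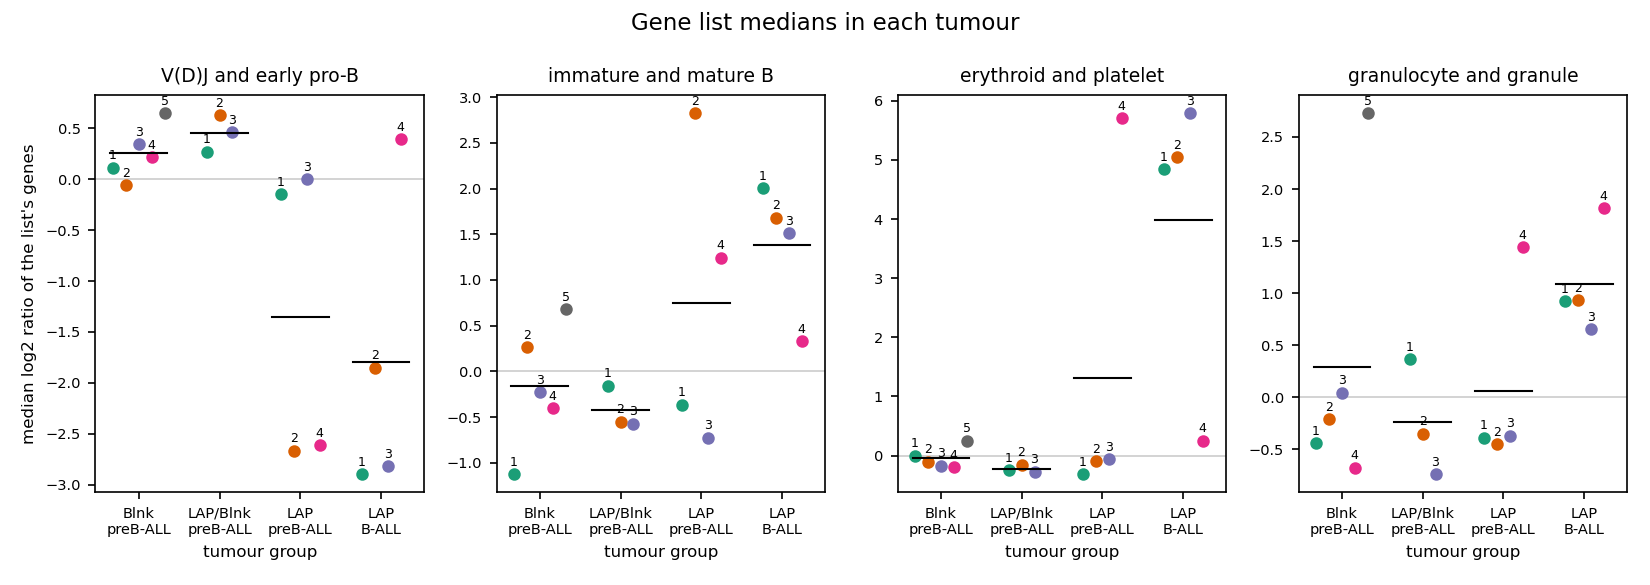
Median log2 ratio, to the median of the 16 tumours, of the genes of 4 lists by tumour group, each point a tumour with its replicate number and each line a group mean (n = 5, 3, 4 and 4). The erythroid and platelet median exceeds 4 in LAP B-ALL 1, 2 and 3 and in LAP preB-ALL 4 (5.70).

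Whether the LAP effect in cells recurs in tumours was asked with the genes changed at least 2-fold in BKO408 cells. Of the 28 higher genes, which include Ccl9, Slpi and Lyz2, 10 were higher and 18 lower in LAP/Blnk than in Blnk tumours, with a median of -0.14 (camera p = 0.578; p = 0.715 with an estimated correlation). Of the 19 lower genes, which include Dntt, Rag1 and Irf4, 8 were higher and 11 lower, with a median of -0.09 (camera p = 0.312; p = 0.404 with an estimated correlation). No gene was called by limma in both comparisons, but with 3 genes called in tumours, and 989 under an unadjusted p of 0.05, a shared count of 0 decides nothing. Across genes, which are not independent replicates, the log2 differences had a Pearson r of -0.033, and 21 of the 47 genes had the same sign.

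The difference of both LAP effects, tumours minus cells, was tested gene by gene, with 180 genes passing, 89 higher and 91 lower. The highest were Fgf12 (3.51 ± 0.18), Cebpb (3.49 ± 0.54, adjusted p = 0.00674), Robo3 (3.23), Mirt1 (2.31) and B3galt1 (2.25), and the lowest Klf2 and Ptpn22 (-2.55 each), Gfi1 (-2.52), Cybb (-2.41) and Cldn10 (-2.27). With separate variances for tumours and cells Fgf12, Robo3 and B3galt1 passed, and Cebpb, Mirt1 and the 5 lowest did not. Mirt1, Ptpn22, Cybb and Cldn10 also did not pass without any 1 of the 8 cell-line arrays, and Cebpb reversed to -0.48 with the probe set chosen by name. By camera with the preset correlation 13 of 23 lists passed, and none with an estimated one (smallest adjusted p = 0.0683, pre-BCR genes). Cholesterol genes lay higher in the difference (adjusted p = 9.61e-08; adjusted p = 0.278 with an estimated correlation; 2 higher, 4 adjusted over the list alone), and monocyte genes and Myc and ribosome genes lower (adjusted p = 6.69e-06 each; adjusted p = 0.451 and 0.508 with an estimated correlation). Pre-BCR, V(D)J, B-lineage factor and cell-cycle genes also lay higher, and interferon, immediate early, granulocyte, glycolysis, T-cell and unfolded protein genes lower (adjusted p from 3.99e-04 to 0.0489). The count was 47 with separate variances for tumours and cells, whose spreads differ, and 820 with array weights. It was 83, 88, 90 and 86 without BKO408 cells 1 to 4, 84, 75, 84 and 80 without BKO408 cells with LAP 1 to 4, and 348, 360, 319 and 691 without Blnk tumours 1, 3, 4 and 5. Of 56 splits of the 8 tumours 6 gave as many genes. Every split kept the cell-line difference in the contrast, so this share cannot decide on chance.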

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

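Chosen only after the result was seen were the tests of array scaling and of a copy gain for chromosome 19, the tests on LAP B-ALL 4 and the tests on LAP preB-ALL 2 and 4. The tests of other splits of the samples and of donor DNA around Blnk were planned before. A first test of the copy gain, planned before, chose genes by a spread that the LAP/Blnk tumours add to (0.933), and was replaced.

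Genes of chromosome 19 lay higher in the 3 LAP/Blnk tumours, by 0.24 in the median against Blnk tumours. Scaling of whole arrays would move the other chromosomes as well, and their median difference was -0.027. The Blnk locus lies in part 3 of 4 equal parts of the chromosome. All 4 lay over 0.1 (0.48, 0.11, 0.13 and 0.24), so the rise was not confined to the part with Blnk. DNA of another mouse strain around the locus could be shared, since both groups carry the Blnk knockout, and how far it reaches is unknown. The parts therefore do not decide on such DNA. A gain of a whole copy in these tumours stays open. Among genes chosen by their spread over the other 13 tumours the median was 0.51 on chromosome 19 and -0.079 elsewhere, where 1 added copy gives 0.58. The 90th percentile of these genes, an upper tail that spread widens, was 0.917 on chromosome 19 and 0.292 elsewhere. With the probe set chosen by name, however, part 2 of the chromosome rose by 0.06 only. DNA copies were not measured, and a biological effect of the genotype on this chromosome was not tested.

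The tumour labelled LAP B-ALL 4 had the Cebpb probe set of the largest spread at -3.11, within the range of Blnk tumours and below all other LAP tumours, so an exchange of labels with LAP preB-ALL 4 does not explain it. Dilution by cells without Vpreb1 is argued against by Vpreb1, which differed by 0.036 from the Blnk tumour median. The other LAP B-ALL tumours had Vpreb1 low, however. Dilution by pre-B cells, which would bring Vpreb1, cannot be decided by this gene and stays open. The array correlated best with the mean of Blnk tumours (r = 0.175 across genes, against 0.034 with LAP/Blnk tumours, -0.060 with LAP B-ALL and -0.187 with LAP preB-ALL), but without Blnk tumour 5 this fell to 0.056, and single Blnk tumours gave -0.082, -0.014, 0.078, 0.145 and 0.288. Whether this is a tumour without the transgene under a LAP label is therefore undecided. Spsb4 was at -1.15 in this tumour, as in the other tumours of LAP mice with Blnk (all at or below -0.72) and not in Blnk tumours (0.72 to 2.84). It was higher in LAP/Blnk tumours, which carry the transgene, than in LAP preB-ALL, so a low value does not mark the transgene. Spsb4 was also picked from the genes lower in LAP preB-ALL than in Blnk tumours in these same data. Loss or silencing of the transgene was not tested and stays open.

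LAP preB-ALL 2 and 4 had Vpreb1 at -8.49 and -8.89 and Rag1 at -6.24 and -5.66, near the values of LAP B-ALL 1, 2 and 3. Dilution of tumour cells by cells outside the B lineage is argued against by Cd79a, a B-lineage gene whose lower value on these arrays was -0.59. Erythroid markers nevertheless lay at 5.70 in LAP preB-ALL 4. Dilution by other B cells, which would keep Cd79a, cannot be decided by this gene and stays open. An exchange of tumour type labels between the LAP groups cannot be told apart from tumours of mixed stage, since 1 LAP B-ALL array held Vpreb1 at the pre-B level where 2 LAP preB-ALL arrays lacked it, and the labels give no other mark of stage. Across genes LAP preB-ALL 4 had r = 0.847 with the mean of LAP B-ALL and LAP preB-ALL 2 had 0.326, while LAP B-ALL 4 had -0.187 with the mean of LAP preB-ALL, so a single wrong label of LAP preB-ALL 4, which needs no partner, stays open too. A biological difference in stage among LAP tumours stays open and was not tested.

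Single samples far from the others of their group were found in 16 of 175 tests, each of a probe set, gene, list or chromosome within a group. Chance gives about 1 in 20 for independent tests, but these share genes and samples, so both shares cannot be compared. In LAP preB-ALL 2 the Cebpb probe set was low at -1.41 and the Blnk probe set high at 1.45. Vpreb1 was low in Blnk tumour 2 (-0.45) and, against its group, high in LAP B-ALL 4 (0.14), as were Rag1 (2.00) and Mycn (3.88) in LAP B-ALL 4. Dntt was high in Blnk tumour 3 (5.79). In Blnk tumour 5 the medians of granulocyte genes (2.73), stromal markers (1.52), B-lineage transcription factors (0.59) and plasma-cell genes (0.22) were high. LAP preB-ALL 4 was high in erythroid markers (5.70) and granulocyte genes (1.44), and LAP B-ALL 4 was low in erythroid markers against its group (0.26). Pre-BCR genes were low in LAP B-ALL 3 (-0.079), and monocyte genes were low in BKO408 cells with LAP 1 (-0.022).

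The LAP effect differed between tumours and cells in 180 genes. Of the 56 splits of the 8 tumours 6 gave as many, and another split gave 456. Every split kept the labels of the cells and still subtracted the measured cell-line difference. These counts therefore cannot decide on chance, which is not excluded. Outside the named genes, 1306 of 15588 probe sets without a gene symbol changed with LAP in BKO408 cells, 19 of them at least 2-fold.

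For the 3820 genes of the cell line 1 of 35 splits, the real one, gave as many and the highest other gave 0. For the 406 genes of LAP/Blnk tumours against LAP preB-ALL it was also the real one of 35, and the highest other gave 50. Such a share is the smallest that 35 splits allow and lies under the bound fixed before, so it argues against chance without excluding it. The 406 became 50 with only these groups in the fit, and chromosome 19 held 119 of the 272 higher genes. For the 14 genes of LAP preB-ALL against Blnk tumours 4 of the 100 splits drawn gave as many, a share just under the bound fixed before. The highest other split gave 80, which points to a structure of the samples, and no gene passed without LAP preB-ALL 2. Chance is therefore not excluded for these 14 genes. Chance cannot be excluded for the 3 genes of LAP/Blnk against Blnk tumours, where 3 of 56 splits gave as many and the highest other gave 5. For LAP B-ALL against LAP preB-ALL the real split gave 0, so 35 of 35 splits had to give as many and the count says nothing about chance. The split of LAP B-ALL 1, 2 and 3 with LAP preB-ALL 4 against the rest gave 1629, which points to a structure of the samples other than their labels, and those are the 4 tumours with erythroid transcripts.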

How the results depend on the processing

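Array medians set to 0, a probe set chosen by name, the more variable genes, a trend of the variance, Xist as a covariate, tumours without LAP B-ALL 4 and separate variances were chosen after seeing the data. The cause was not tested for any change below, except that a 2-fold threshold leaves fewer calls by construction. Leaving out arrays moved counts both up and down.

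The 3820 genes of the cell line stayed within 1.5 times under all alternatives except a 2-fold threshold (47) and all 24 arrays in the fit (21), and ranged from 3080 to 3515 with a replicate left out. The 3 genes of LAP/Blnk against Blnk tumours became 33 with array weights, 29 with quantile normalisation and 5 without LAP B-ALL 4. Leaving out a replicate gave 2 to 13, with 8 and 13 without LAP/Blnk tumours 1 and 3. The 406 genes of LAP/Blnk tumours against LAP preB-ALL became 177 at 2-fold, 262 in the more variable genes, 50 with only these groups in the fit (36 shared) and 623 without LAP B-ALL 4. Leaving out a replicate gave 85 to 304, with 132, 134 and 85 without LAP/Blnk tumours 1, 2 and 3 and 237, 215 and 230 without LAP preB-ALL 1, 3 and 4.

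The 14 genes of LAP preB-ALL against Blnk tumours became 24 with array weights, 2 with quantile normalisation (50% higher against 7.14%), 0 with the mean of probe sets, 8 at 2-fold, 1 with the probe set chosen by name, 3 in the more variable genes, 5 with only these groups, 4 with Xist and 107 without LAP B-ALL 4. Leaving out a replicate gave 0 to 17, with 4, 0 and 5 without LAP preB-ALL 1, 2 and 3 and 8, 2, 2 and 6 without Blnk tumours 1 to 4. LAP B-ALL against LAP preB-ALL gave 4 with array weights and 0 to 291 with a replicate left out, 5 without LAP B-ALL 4 and 291 without LAP preB-ALL 4. The 180 genes of the difference of both LAP effects became 820 with array weights, 67 at 2-fold, 17 with all 24 arrays and 47 with separate variances (43 shared). Quantile normalisation moved the share of higher genes in it from 49.4% to 64.7%. Leaving out a replicate gave 75 to 691, with 83, 88, 90 and 86 without BKO408 cells 1 to 4, 84, 75, 84 and 80 without BKO408 cells with LAP 1 to 4, and 348, 360, 319 and 691 without Blnk tumours 1, 3, 4 and 5.

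The median of the genes higher in the cell line ranged in tumours from -0.204 to -0.0233 with a replicate left out and that of the lower genes from -0.249 to -0.00732, the latter at 0.0147 with quantile normalisation. With the probe set chosen by name the sign turned for Xbp1 (-0.0016), Fkbp11 (-0.0023) and Top2a (0.085) in the cell line and for Cebpb in the difference of both LAP effects (-0.48). Of 132 values of named genes 94 lost their call with all 24 arrays in the fit, and of 11 in the difference of both LAP effects 7 did with separate variances. Over all settings 496 values of named genes lost a call, 89 gained one and 4 reversed. Of 138 list tests 47 lost their call with an estimated correlation.

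A block for the replicate number gave 3427 genes in the cell line and 0 in each tumour comparison. In tumours that fit held only the groups compared and the replicate numbers they share. The counts of 0 therefore do not separate the block from the samples left out. Same-numbered samples had r of 0.13, 0.26, -0.03 and 0.09 in the cell line, 0.02, -0.12 and 0.38 between LAP/Blnk and Blnk tumours, -0.04, -0.04 and 0.15 between LAP/Blnk tumours and LAP preB-ALL, 0.07, 0.23, 0.38 and -0.11 between LAP preB-ALL and Blnk tumours, and -0.28, 0.04, -0.24 and -0.64 between LAP B-ALL and LAP preB-ALL. In each comparison some samples correlated better with another number, so the numbers do not show pairs.

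The planned pseudocounts, filters on low values, probe sets of the highest mean and the comparison of Blnk tumours with BKO408 cells were not run, because centred ratios keep no level. Signal over background is unknown for the same reason.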

Other observations

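The tests on Cebpb in BKO408 cells with LAP below were chosen only after the result was seen. Mycn, a relative of Myc, varied among tumours of the same group, at 8.20, -0.38, -0.39, 3.81 and 1.74 in Blnk tumours 1 to 5, at 3.45, 5.55 and -0.37 in LAP/Blnk tumours and at 3.88 in LAP B-ALL 4, and lay between -0.34 and 0.29 in the other LAP tumours. Blnk tumour 1, with the highest Mycn, had Myc at -3.70, below the other 15 tumours. Dntt was high in Blnk tumour 3 (5.79) and LAP/Blnk tumour 3 (3.36). Ighm was high in Blnk tumour 2 (4.80) and Jchain in LAP preB-ALL 2 (6.08). Gata1, an erythroid factor, was at 3.25, 3.20, 4.36 and -0.24 in LAP B-ALL 1 to 4 and at -0.02, -0.21, -0.46 and 4.16 in LAP preB-ALL 1 to 4. Erg was at -3.59, -4.30, -3.92 and -0.04 in LAP B-ALL and at 0.04, -4.65, -0.18 and -3.52 in LAP preB-ALL.

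Cebpb was not higher by a test in BKO408 cells with LAP. Probe sets outside the LAP sequence remain open, since the probe set of the largest spread separated LAP/Blnk from Blnk tumours by a gap of 1.91 but the virus and the transgene may carry different parts of the gene. Cultures that did not differ from control are argued against by the 3820 genes that the real split called. That count shows a difference between both sets of arrays and does not show that LAP was introduced. Whether the replicates were separate cultures is not given, so a difference between cultures unrelated to LAP stays open.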
